A study of Cucurbita moschata with 6 samples.

How the data were processed

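Poly(A) RNA was sequenced from hypocotyls of pumpkin (Cucurbita moschata) seedlings at the stage of open cotyledons, per the labels. The seedlings were grown with 14 h of light at 28 °C and 10 h of dark at 18 °C, and stranded paired-end libraries with a mean insert of 300 bp were made, per the labels' protocols. The 6 libraries fall into 2 groups of 3 by their titles, SCK and SR. The labels do not spell out either name. The series text gives 1 treatment and 1 control, and CK is a customary abbreviation for a control in agronomy, so SCK is read here as the control. The labels' treatment protocol, far-red light for 120 s, stands on all 6 samples. Nothing in the labels says that replicates came from separate plants or batches, so p-values measure the spread between these samples, which may be technical.

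The authors deposited 1 table with whole-number counts and FPKM values for 32205 genes, per the file headers, and 1 count and 1 FPKM column for each of the 6 libraries was used. HISAT and StringTie are named among the tools, per the submitters' processing notes, without versions or roles. The genome build, the annotation, the use of strand and the handling of reads shared by near-identical gene copies are not given in the sources used here, so values of close paralogs are uncertain. Gene identifiers, positions and products are those of the deposited table, where each product carries the species name of a protein, and how it was assigned is not given in the sources used here; 2723 genes have no product there. A further 6 columns of values match no sample of the series and were not used. The deposited counts hold no normalization that could be seen: totals ran from 52300725 (SCK replicate 2) to 72356397 (SR replicate 2). The value 4 occurred 1350 times, against 567 times for 3 and 516 times for 5, and 8 and 12 were likewise more frequent than their neighbours. One read pair may therefore be worth about 4 deposited counts, which would divide these depths by 4. The deposited FPKM values were 0.0001 in all 28770 places where the count was 0, so an offset replaced 0 there.

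The design fixed before the data were examined planned limma on log2 FPKM, with edgeR in its place if the table held counts. It did, so the main test was edgeR 4.0.16 (glmQLFit and glmQLFTest with TMM factors, R 4.3.3) on the counts as deposited, SR against SCK, with group as the only term. Genes entered with an FPKM of at least 1 in at least 3 libraries, which left 23509. Calls have a Benjamini-Hochberg adjusted p under 0.05, and a second count takes those with an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were taken as the fold change over the root of the F statistic. Group values are the mean ± SD of deposited FPKM. A fold against a group with a count of 0 in every library was set against a floor of 3 read pairs over the group, taken as 12 deposited counts. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

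Before the data were examined, 34 gene lists were fixed as patterns on product names, among them markers of other tissues and of handling stress. They were tested on log2(FPKM + 1) with camera of limma 3.58.1 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts adjusted over the list alone use Benjamini-Hochberg within a list. GO and KEGG terms of the deposited table with 10 to 500 tested members were tested with a one-sided Fisher's exact test, separately for genes that rose and fell, against all tested genes with an annotation of that kind, and adjusted over both directions. The genes named in the text follow a rule fixed in advance. It takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, with a group mean of at least 5 FPKM and a product name. It adds the 2 members of each list with the smallest adjusted p, and for light receptors and PIF, HD-Zip II, early auxin response, gibberellin, expansins and xyloglucan endotransglucosylases also the most abundant member. Other genes are named only where a count is small, or said to have been chosen after their values were seen. A called member of the list of auxin synthesis and transport is counted there but not reported here by name.

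On counts simulated from the real means, totals and dispersions, with 200 genes changed among 23509, edgeR recovered 22 of 100 genes changed 2-fold and 83 of 100 changed 4-fold, with 6 false among 111 calls. DESeq2 recovered 64 and 97, with 91 false among 252 calls, and limma 16 and 84, with 7 false among 107. These shares belong to a setting with 200 changed genes and need not hold where more genes change. Camera called the 1 shifted list and 0 of the unchanged lists among 34. Every member of the shifted list was raised by 1 on the log2 scale. The lists called in the real data have median log2 changes of 0.19 to 0.75 in size, and shifts of that size were not simulated. Correlation between genes was not among the simulated properties. The simulation therefore cannot show how often camera calls unchanged lists whose members move together. The alternatives were DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1 and 0.1, other filters, other scalings, the replicate number as a block, robust priors, a test against a 1.2-fold change, and leaving out each library in turn. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.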

Results

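Transcripts were measured in the hypocotyl, the stem below the cotyledons, of pumpkin seedlings in a series on far-red light and hypocotyl elongation. The 2 groups, SCK (read as the control) and SR, had 3 libraries each. Deposited counts summed to 56261825, 52300725 and 67350441 in SCK replicates 1, 2 and 3 and to 63870714, 72356397 and 66160709 in SR replicates 1, 2 and 3. All changes below are SR relative to SCK, all fold changes are log2 values ± SE from edgeR's quasi-likelihood test, and all adjusted p-values of genes are from that test with Benjamini-Hochberg adjustment. Levels are FPKM as mean ± SD (n = 3). The fold changes use TMM factors and the deposited FPKM values do not, so the log2 changes tend to lie below what the levels beside them give. The median log2 change of all tested genes was 0.01 with TMM factors and 0.14 without them. Genes given without an identifier were chosen after their values were seen.

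The comparison of SR with SCK asks which hypocotyl transcripts differ between the treated and the control seedlings. Expansins, pectin-modifying enzymes, the list of cellulose synthesis, and cytoskeleton, cell cycle and ribosomal protein genes were called mostly as rises. The list of cellulose synthesis also holds endoglucanases, which cut cellulose, and its 2 leading rises were of that kind. Genes of light receptors, light signalling, photosynthesis, chlorophyll synthesis and abscisic acid response were called mostly as falls. Expansin-A4-like (CmoCh01G006340) rose from 7.88 ± 2.42 to 67.2 ± 23.5 FPKM, and a CONSTANS-LIKE 5-like zinc finger gene (CmoCh10G004490) fell from 570 ± 69.2 to 226 ± 10.1 FPKM. In all, 3375 of 23509 tested genes passed an adjusted p of 0.05, of which 1692 rose and 1683 fell. Among these, 840 rose and 610 fell at least 2-fold, 1450 together. The 3 SR values all lay on one side of the 3 SCK values in 40.6% of tested genes, where chance gives 10%. The first principal component, with 47.0% of the variance, separated the groups, and the second, with 23.1%, spread the replicates within them.

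The number of calls depended on single libraries. Without SCK replicate 3, edgeR called 0 genes, with 5558 at an unadjusted p under 0.05, while DESeq2 called 3637 and limma 8. In that edgeR fit no list below has members called over all tested genes, and counts adjusted over the list alone were not made. SCK replicate 3 lay between SCK replicates 1 and 2 in 1161 of the 1196 genes that differed at least 2-fold between those. If that library was a blend of the other SCK libraries, the control would hold fewer than 3 independent samples. The p-values of the main test would then tend to be too small. Without SR replicate 3 edgeR called 542 genes, without SCK replicate 1 1576, without SCK replicate 2 1667 and without SR replicate 2 1981. All 3375 genes kept their sign in each of these fits. In 3359 of them the SCK and SR values did not overlap, so leaving out 1 library could hardly turn a sign. Without SR replicate 1, 3437 genes were called. Without SR replicate 3 the members called were fewer in every list except HD-Zip II. Without TMM factors the median log2 change of all tested genes was 0.14, against 0.01 with them, and 2602 genes rose while 1155 fell.

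**Figure D1:**
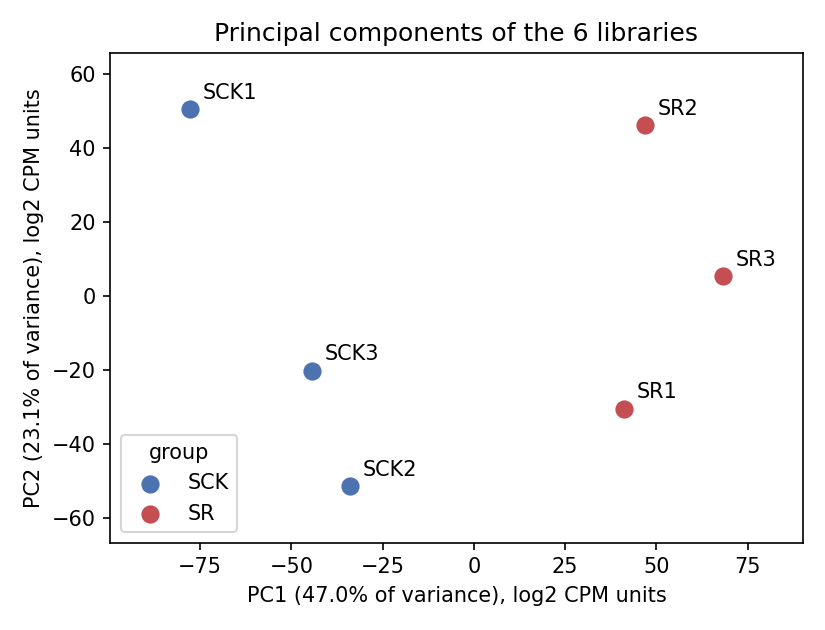
Each point is 1 library, placed by the first and second principal components of log2 CPM (axes, with the share of variance) and coloured by group. SCK and SR libraries are apart on the first component (47.0%), and SCK replicate 3 sits between the other SCK libraries on both axes.

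Light receptors and PIF factors, the bHLH factors that bind phytochrome, held 9 falls and 0 rises among 26 tested members (11 falls adjusted over the list alone). PIF1-like (CmoCh08G000550, chromosome 8, 341064 to 344740) fell by 0.86 ± 0.10 on the log2 scale, from 62.8 ± 5.65 to 37.9 ± 1.18 FPKM (adjusted p = 0.0116). Cryptochrome-1-like (CmoCh01G016510), a blue light receptor, fell by 1.39 ± 0.22 (adjusted p = 0.0160), and the most abundant member, cryptochrome-1 (CmoCh17G001640), fell by 0.53 ± 0.13 from 159 ± 4.62 FPKM (adjusted p = 0.0403). That call of the most abundant member was lost in each edgeR fit without 1 library (adjusted p = 0.0515 to 0.143), without TMM factors (0.0855) and by limma (0.0720, or 0.0837 rescaled to a common total and 0.104 with quantile normalization). The other falls were PIF4-like, phytochrome B-like, phytochrome E-like, phototropin-1-like, phototropin-2-like and another cryptochrome-1. Camera called the list (adjusted p = 0.00102), with adjusted p = 0.657 with an estimated correlation. EdgeR called 2 falls without SR replicate 3 and 5 without SCK replicate 1.

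Of 101 light signalling genes, 18 fell and 1, CONSTANS-LIKE 6, rose (25 and 4 adjusted over the list alone). CONSTANS-LIKE genes encode B-box zinc finger proteins. A CONSTANS-LIKE 5-like gene on chromosome 11 (CmoCh11G004140, 2033089 to 2034998) fell by 1.84 ± 0.17, and its namesake on chromosome 10 (CmoCh10G004490, 2020058 to 2021922) fell by 1.47 ± 0.17 (adjusted p = 0.00942 and 0.0109). The falls also included genes annotated as COP1, the ubiquitin ligase that represses photomorphogenesis, its partners SPA1-RELATED 2 and 3, and B-box 24. Camera called this list too (adjusted p = 0.000294), with adjusted p = 0.427 with an estimated correlation. EdgeR called 0 rises and 3 falls without SR replicate 3, 11 falls without SCK replicate 1, 3 rises without SR replicate 1, and 4 rises and 15 falls without TMM factors. Among 37 clock genes, 3 fell (APRR9, APRR1 and APRR5) and 2 rose (EARLY FLOWERING 3 and APRR2), the same numbers as adjusted over the list alone. APRR9 (CmoCh02G011820) fell by 1.06 ± 0.16 and APRR1 (CmoCh11G001820) by 0.57 ± 0.10, and the list was not called (adjusted p = 0.198). Without SR replicate 3 neither gene passed (adjusted p = 0.0606 and 0.0726), nor did APRR1 by limma (0.0576). Clock genes called by edgeR were 0 rises and 1 fall without SR replicate 3, 2 and 5 without SR replicate 1, 0 rises without SCK replicate 2 and 1 rise without each of SCK replicate 1 and SR replicate 2. Of 11 genes taken for class II HD-Zip factors, 1 fell (1 adjusted over the list alone), HAT3.1 (CmoCh04G004960, log2 change -0.84 ± 0.10), a homeodomain protein outside that class. The most abundant, HAT22-like (CmoCh07G006240), was at 130 ± 12.2 and 114 ± 19.4 FPKM with adjusted p = 0.226, and the list was not called (adjusted p = 0.923). In that list 1 rise was called without SR replicate 2.

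Photosynthesis genes fell in 18 of 79 cases and rose in 0 (27 falls adjusted over the list alone), with a median log2 change of -0.63. This median was -0.36 without SCK replicate 1, -0.49 without TMM factors, -0.43 by limma, -0.41 by limma rescaled to a common total and -0.38 with quantile normalization. An LHCII type 1-like antenna gene (CmoCh03G013760) fell by 1.21 ± 0.18, from 375 ± 10.4 to 178 ± 33.3 FPKM (adjusted p = 0.0142, and 0.0572 without SR replicate 3). A gene for Rubisco activase (CmoCh15G001100), which keeps Rubisco in its active form, fell by 1.88 ± 0.20 from 7.77 ± 1.40 FPKM. Of 26 chlorophyll synthesis genes, 6 fell and 0 rose, with 6 falls adjusted over the list alone. They include chlorophyllide a oxygenase (CmoCh15G006900, log2 change -1.54 ± 0.15), which makes chlorophyll b, and magnesium chelatase subunit ChlH (CmoCh03G000620, -1.36 ± 0.16). Camera called both lists (adjusted p = 3.85e-12 and 0.00691), and with an estimated correlation both had adjusted p = 0.657. SCK libraries also differed among themselves here: the median photosynthesis member stood 0.39 above the SCK mean in SCK replicate 1 and 0.36 below it in SCK replicate 2 on the log2 scale, next to 0.39, 0.65 and 0.71 below it in SR replicates 1, 2 and 3. EdgeR called 1 fall of photosynthesis genes without SR replicate 3, 7 without SR replicate 2 and 9 without SCK replicate 1, and for chlorophyll synthesis 2 without SR replicate 3 and 3 without each of SCK replicates 1 and 2 and SR replicate 2. DESeq2 called 39 falls and 0 rises of photosynthesis genes with all libraries, and 25 falls and 0 rises without SCK replicate 3. In that last setting edgeR and limma each called 0 falls and 0 rises of them.

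Expansins, which loosen cell walls, rose in 7 of 26 cases and fell in 0 (10 rises adjusted over the list alone). Expansin-A4-like (CmoCh01G006340, chromosome 1, 3246744 to 3248140) rose by 2.93 ± 0.34 (adjusted p = 0.0109), and expansin-A16 (CmoCh19G008340) by 1.72 ± 0.20. The most abundant expansin, expansin-A8-like (CmoCh15G001780), was at 273 ± 34.2 and 288 ± 195 FPKM (adjusted p = 0.942). Pectin-modifying enzymes rose in 20 and fell in 5 of 93 cases (22 and 6 adjusted over the list alone). Pectate lyase 5 (CmoCh05G000620) rose by 2.68 ± 0.27 and pectate lyase 8 (CmoCh08G010060) by 2.11 ± 0.24, while the falls were 3 pectinesterases, a polygalacturonase and a pectin acetylesterase. In the list of cellulose synthesis, 12 of 55 members rose and 1, cellulose synthase-like H1, fell (20 and 1 adjusted over the list alone). Endoglucanase 6-like genes on chromosome 16 (CmoCh16G005990) and chromosome 4 (CmoCh04G007380) rose by 1.95 ± 0.22 and 2.34 ± 0.31. Endoglucanases cut cellulose chains, and how many of the 12 rises are cellulose synthases was not counted. Camera called these lists (adjusted p = 0.00366 for expansins, 0.00815 for pectin and 0.00232 for cellulose), with adjusted p = 0.657, 0.657 and 0.666 with an estimated correlation. EdgeR called 4 rises of expansins without each of SCK replicates 1 and 2 and SR replicates 2 and 3. Pectin enzymes gave 4 rises and 1 fall without SR replicate 3, 11 and 3 without SCK replicate 1 or 2, and 3 falls without SR replicate 2. Rises in the list of cellulose synthesis were 2 without SR replicate 3, 4 without SR replicate 2, 5 without SCK replicate 1, 6 without SCK replicate 2 and 20 without SR replicate 1. Its fall was not called without SCK replicate 2 or any of the SR replicates. Without TMM factors that list gave 16 rises and 0 falls. DESeq2 called 10 rises and 0 falls of expansins with all libraries, and 9 and 0 without SCK replicate 3, where edgeR and limma each called 0 and 0.

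Xyloglucan endotransglucosylases, which cut and rejoin wall xyloglucan, held 4 rises and 2 falls among 33 (7 and 2 adjusted over the list alone). The rises were proteins 6, 7, 8 and 23, and the falls proteins 28 and 30. Protein 7 (CmoCh04G009090) rose by 2.27 ± 0.30 to 156 ± 64.7 FPKM and protein 28 (CmoCh04G022400) fell by 1.41 ± 0.18 to 120 ± 31.1 FPKM. The most abundant, protein 22-like (CmoCh10G004370), was at 252 ± 117 and 267 ± 25.1 FPKM (adjusted p = 0.949), and the list was not called (adjusted p = 0.602). Lignin and xylem wall genes rose in 10 and fell in 4 of 68 cases (12 and 4 adjusted over the list alone). Laccase-4-like (CmoCh14G000810) rose by 1.14 ± 0.16 and a caffeoylshikimate esterase-like gene (CmoCh18G002550) fell by 2.11 ± 0.25, and the list was not called (adjusted p = 0.0853). The other falls were caffeoylshikimate esterases and the cinnamoyl-CoA reductase-like gene SNL6. Class III peroxidases rose in 4 and fell in 1 of 44 cases, as also adjusted over the list alone, led by peroxidase 47 (CmoCh03G000160, log2 change 3.05 ± 0.48) and peroxidase 45-like (CmoCh01G016130, 2.26 ± 0.49), with adjusted p = 0.988 for the list. Peroxidases 31-like and 51-like also rose, and peroxidase 21-like fell. Aquaporins, the water channels, rose in 3 and fell in 6 of 37 cases (5 and 6 adjusted over the list alone; list adjusted p = 0.0991). PIP1-4 (CmoCh04G001640) fell from 875 ± 89.1 to 257 ± 76.6 FPKM, and PIP1-1-like (CmoCh06G002300) rose from 1.35 ± 0.12 to 5.03 ± 0.08 FPKM, as did genes named NIP2-1-like and PIP2-7-like. Without SCK replicates 1 and 2 and SR replicates 1, 2 and 3 in turn, edgeR called 3, 2, 9, 3 and 1 rises and 1, 2, 1, 2 and 1 falls of xyloglucan endotransglucosylases. In that order lignin and xylem genes gave 7, 7, 8, 3 and 1 rises and 1, 2, 2, 1 and 2 falls (13 and 2 without TMM factors). Peroxidases gave 2, 1, 5, 1 and 0 rises and 3, 1, 1, 0 and 0 falls, and aquaporins 2, 2, 3, 1 and 1 rises and 3, 3, 7, 5 and 3 falls (4 and 4 without TMM factors). Peroxidase 47 did not pass without SR replicate 3 (adjusted p = 0.0572), and peroxidase 45-like did not pass without SCK replicate 1 or 2 or SR replicate 2 or 3 (0.0696, 0.0753, 0.0556 and 0.0880) or with limma on quantile-normalized values (0.0522).

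Cytoskeleton genes rose in 23 and fell in 3 of 145 cases (32 and 5 adjusted over the list alone). Kinesin KIN-14N (CmoCh01G012070), a microtubule motor, rose by 1.25 ± 0.12. A tubulin alpha-3 gene, the kinesin KIN-14B and the EB1-family protein RP/EB fell. Cell cycle genes rose in 23 and fell in 5 of 150 cases (28 and 6 adjusted over the list alone). Cyclin-D3-3-like (CmoCh12G005100), a cyclin of the entry into DNA synthesis, rose by 2.57 ± 0.35 from 0.91 ± 0.10 to 6.02 ± 2.40 FPKM, and a linker histone H1 gene (CmoCh03G007250) fell by 1.30 ± 0.18, a call lost without SR replicate 3 (log2 change -1.32). The other falls were a histone H1-like gene, histone H3.v1-like, the inhibitor SMR6-like and the kinase CDKG-2-like. Cytosolic ribosomal protein genes rose in 46 and fell in 8 of 250 cases (60 and 9 adjusted over the list alone), such as L3-2 (CmoCh04G019620, log2 change 0.99 ± 0.13) and L9-like (CmoCh02G011030, 0.91 ± 0.13). Camera called the cytoskeleton, cell cycle and ribosome lists (adjusted p = 0.00102, 0.00159 and 1.09e-06), with adjusted p = 0.708, 0.657 and 0.666 with an estimated correlation. Without SR replicate 3, edgeR called 5 rises of cytoskeleton genes, 2 rises and 3 falls of cell cycle genes and 2 rises of ribosomal protein genes. The rises of these lists were 10, 10 and 15 without SCK replicate 1, 13, 11 and 14 without SCK replicate 2, 14, 11 and 23 without SR replicate 2 and 42, 24 and 28 without SR replicate 1. Falls of cytoskeleton genes were 1 without SCK replicate 2 and 0 without SR replicate 3, and those of ribosomal protein genes 1 and 0 without SCK replicates 1 and 2 and 2 and 0 without SR replicates 2 and 3. Without TMM factors edgeR called 36 rises and 2 falls of cytoskeleton genes and 73 rises and 3 falls of ribosomal protein genes.

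Auxin synthesis and transport genes rose in 7 of 28 cases and fell in 0 (8 and 1 adjusted over the list alone; list adjusted p = 0.0609). Auxin transporter-like protein 3 (CmoCh15G007120), an influx carrier, rose by 3.25 ± 0.40 from 2.72 ± 0.50 to 28.7 ± 13.9 FPKM, and auxin efflux carrier component 4-like (CmoCh04G021920) rose by 1.01 ± 0.17. Early auxin response genes rose in 6 and fell in 6 of 119 cases (5 and 5 adjusted over the list alone; list adjusted p = 0.475). SAUR68-like (CmoCh19G007850) fell by 2.74 ± 0.40 and auxin-induced protein 22B-like (CmoCh08G010900) by 0.72 ± 0.12. The most abundant, AUX28-like (CmoCh08G003030), was at 654 ± 179 and 838 ± 241 FPKM (adjusted p = 0.664). Gibberellin genes rose in 4 and fell in 4 of 35 cases (5 and 4 adjusted over the list alone; list adjusted p = 0.475). Gibberellin-regulated protein 4-like (CmoCh14G005980, chromosome 14, 3030163 to 3031199), the most abundant, rose by 2.44 ± 0.35 from 229 ± 12.3 to 1378 ± 664 FPKM (adjusted p = 0.0137). Gibberellin 3-beta-dioxygenase 4 (CmoCh04G001450), of the enzyme family that makes active gibberellins, rose by 1.37 ± 0.14 (adjusted p = 0.0104). An ent-kaurene oxidase and a DELLA protein also rose, and a gibberellin 20-oxidase, a 3-beta-dioxygenase 1-like gene, an ent-kaurenoic acid oxidase and a GID1C-like receptor fell. Leaving out SCK replicates 1 and 2 and SR replicates 1, 2 and 3 in turn gave 3, 2, 6, 5 and 2 rises and 0 falls of auxin synthesis and transport genes by edgeR. In that order early auxin response genes gave 2, 1, 11, 6 and 0 rises and 2, 5, 5, 5 and 1 falls (8 and 5 without TMM factors). Gibberellin genes gave 3, 2, 5, 4 and 2 rises and 2, 2, 3, 2 and 0 falls (5 and 2 without TMM factors). Protein 22B-like did not pass without SR replicate 3 (adjusted p = 0.0633).

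**Figure D2:**
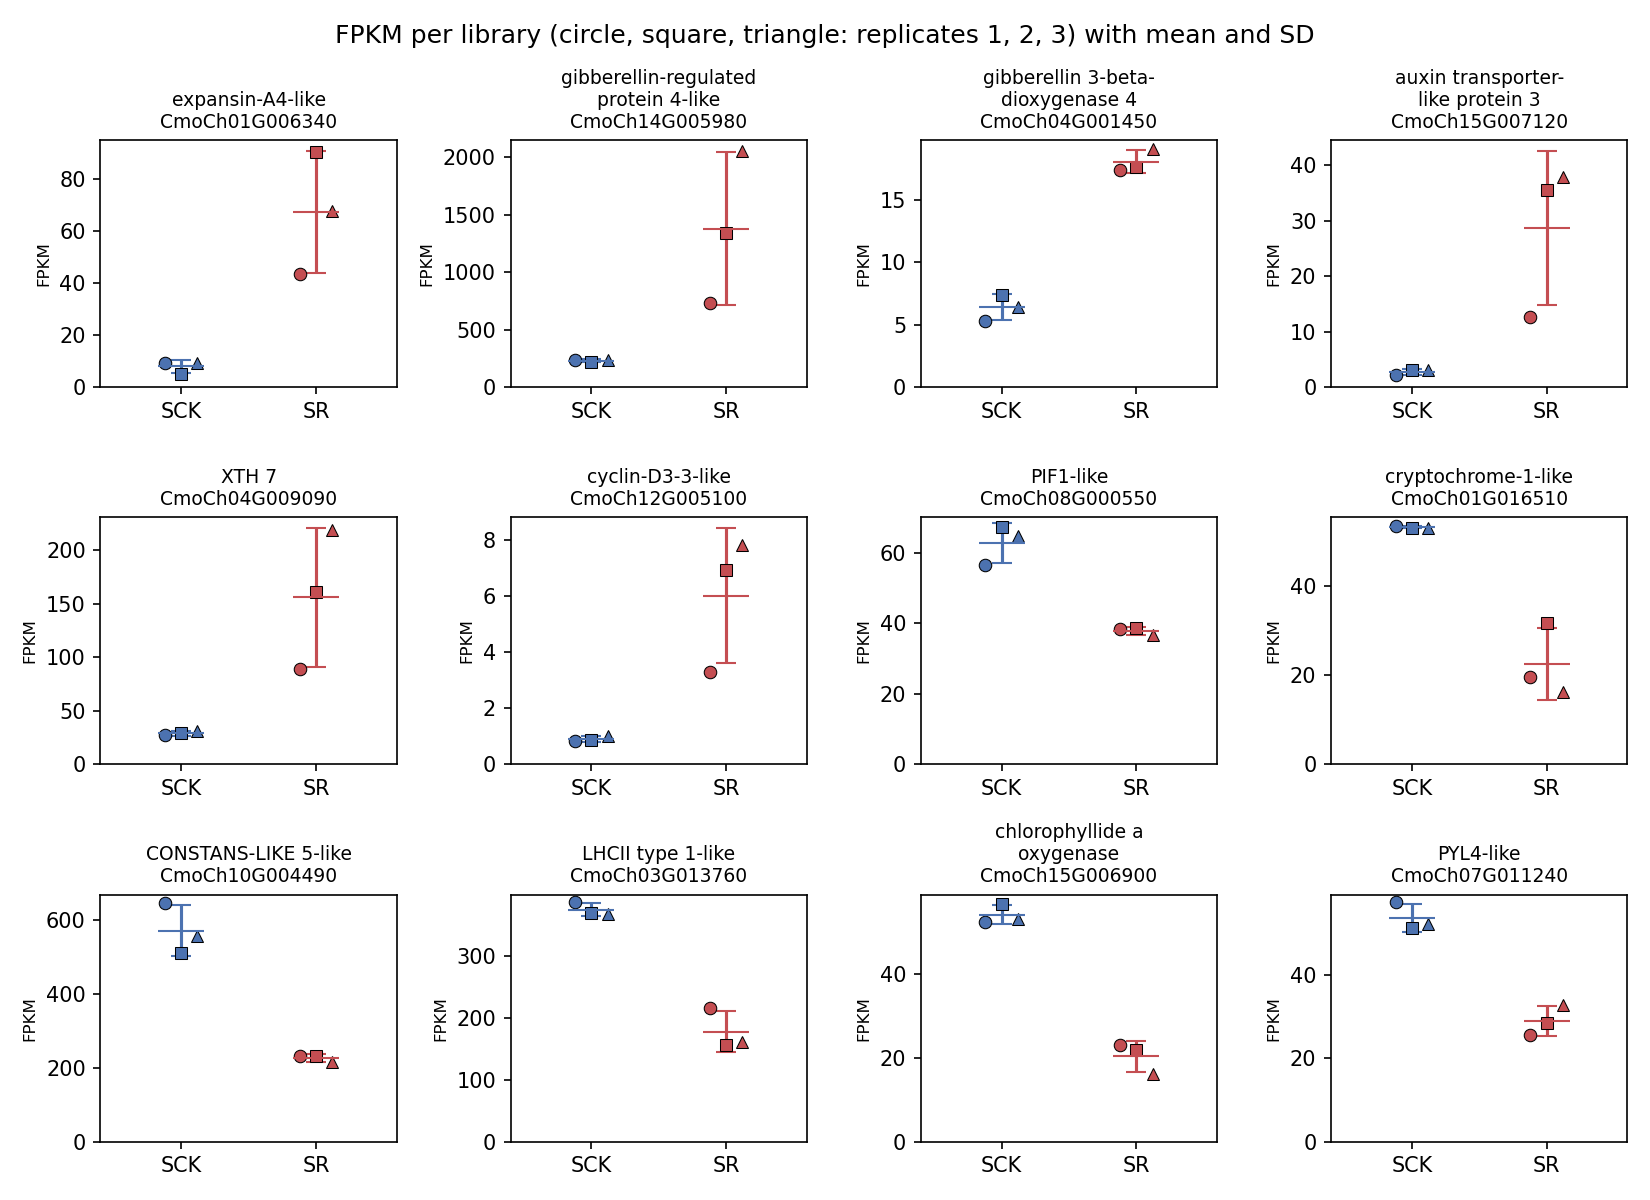
Each panel plots the FPKM of 1 gene (vertical axis from 0) in the SCK and SR libraries, with symbols for the replicates and bars for mean ± SD (n = 3). The 12 genes were picked from those named in the text, and in each the groups do not overlap, as in expansin-A4-like (7.88 ± 2.42 and 67.2 ± 23.5 FPKM).

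Abscisic acid genes fell in 7 of 57 cases and rose in 0 (6 falls adjusted over the list alone), with PYL4-like (CmoCh07G011240), a receptor, down by 1.03 ± 0.13 and PYL9-like (CmoCh14G021660) by 0.77 ± 0.12. Camera called this list (adjusted p = 0.000396), with adjusted p = 0.427 with an estimated correlation. EdgeR called 2 falls of abscisic acid genes without SR replicate 3 and 3 without SCK replicate 2, and 2 and 1 rises without SR replicates 1 and 2. PYL9-like did not pass without SR replicate 3 (adjusted p = 0.0519). Ethylene genes rose in 12 and fell in 18 of 137 cases (16 and 23 adjusted over the list alone; list adjusted p = 0.314). The factor ERF014 (CmoCh04G024610) rose by 2.58 ± 0.24, and an ACC oxidase homolog 3-like gene (CmoCh08G010670) fell by 1.28 ± 0.10. Cytokinin genes rose in 4 and fell in 7 of 55 cases (5 and 7 adjusted over the list alone; list adjusted p = 0.798), among them ORR9-like (CmoCh15G006810, log2 change 1.11 ± 0.15) and LOG1-like (CmoCh12G003650, -1.37 ± 0.21), an enzyme that activates cytokinins. The other rises were isopentenyltransferase 3, ARR1-like and APRR2, and some of the falls were clock regulators, APRR9, APRR1 and APRR5. Of 19 brassinosteroid genes 1 fell, BRASSINAZOLE-RESISTANT 1-like (CmoCh12G004350, log2 change -0.44 ± 0.12, adjusted p = 0.0477), and 0 adjusted over the list alone, with list adjusted p = 0.796. Jasmonate and defence genes rose in 11 and fell in 18 of 146 cases (12 and 20 adjusted over the list alone; list adjusted p = 0.232), with a thaumatin-like gene (CmoCh04G024520) up by 1.61 ± 0.21 and thaumatin-like 1b (CmoCh05G003140) down by 0.88 ± 0.12. With SCK replicates 1 and 2 and SR replicates 1, 2 and 3 left out in turn, edgeR called 5, 4, 14, 10 and 6 rises and 13, 9, 20, 14 and 6 falls of ethylene genes. In that order cytokinin genes gave 3, 3, 4, 7 and 1 rises and 6, 6, 8, 6 and 1 falls, and jasmonate and defence genes 4, 3, 12, 5 and 2 rises and 12, 9, 17, 10 and 4 falls. The brassinosteroid list gave 1 rise without SR replicate 2 and otherwise no call, and BRASSINAZOLE-RESISTANT 1-like passed in none of the edgeR fits without 1 library (adjusted p = 0.0654 and above), without TMM factors (0.113) or by limma (0.122, or 0.144 rescaled and 0.111 with quantile normalization). LOG1-like did not pass without SR replicate 3 (0.0589). Without TMM factors the rises and falls were 16 and 15 for ethylene, 6 and 6 for cytokinin, 14 and 14 for jasmonate and defence, and 1 and 0 for brassinosteroid genes.

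The 8 rises taken by the fixed rule include F-box CPR30-like (CmoCh14G005880), which had 0 counts in every SCK library and 107 to 148 in each SR library, at least 24.3-fold higher against the floor. The 65-kDa microtubule-associated protein 6-like gene (CmoCh15G009170, chromosome 15, 4653052 to 4657559) rose by 5.69 ± 0.52, from 0.41 ± 0.16 to 23.6 ± 12.7 FPKM (adjusted p = 0.00942). GATA factor 12-like (CmoCh17G007460) rose by 5.46 ± 0.55 and DC2.15-like (CmoCh06G007930) by 4.44 ± 0.68. A major latex protein-like gene (CmoCh04G010550) rose from 0.44 ± 0.42 to 17.8 ± 17.2 FPKM. A pectinesterase-like gene (CmoCh17G010390) rose by 4.35 ± 0.79, a cytochrome b5-like gene (CmoCh19G001820) by 4.14 ± 0.29 and a cytochrome P450 85A-like gene (CmoCh04G029400) by 3.86 ± 0.89. The 8 falls taken by the rule include a dynein light chain gene (CmoCh09G008870, log2 change -4.41 ± 1.04), ammonium transporter 3 member 2-like (CmoCh03G006740, -4.37 ± 0.68) and the aminotransferase TAT2 (CmoCh01G012820, -3.90 ± 0.93). Rhodanese-like 15 (CmoCh03G006730) fell from 687 ± 364 to 56.4 ± 44.4 FPKM, the BTB and TAZ domain gene BT1-like (CmoCh18G001780) from 515 ± 125 to 48.3 ± 30.1 and a beta-galactosidase-like gene (CmoCh11G007030) from 425 ± 61.7 to 43.8 ± 16.6. Rhodanese-like 15 (chromosome 3, 5979235 to 5980793) and the ammonium transporter gene (5981770 to 5983684) lie close together on the same strand. Whether their falls are separate was not tested. Flavin-containing monooxygenase 1 (CmoCh02G002850) fell by 3.52 ± 0.85 and homocysteine S-methyltransferase 3-like (CmoCh17G002110) fell by 3.49 ± 0.75. Of these 16 genes, 10, 12 and 0 passed without SCK replicates 1, 2 and 3, and 10, 13 and 7 without SR replicates 1, 2 and 3. The 7 that passed without each library other than SCK replicate 3 were the F-box, microtubule-associated, GATA, DC2.15-like, cytochrome b5-like, BT1-like and beta-galactosidase-like genes. The other 9 had adjusted p = 0.0566 to 0.133 without SR replicate 3. Without SR replicate 2 the DC2.15-like gene was at 3.43 and the pectinesterase-like gene at 3.52, rhodanese-like 15 at -4.51 and the methyltransferase at -4.26, all past the threshold. Without SCK replicate 1 the log2 changes of the dynein, TAT2 and monooxygenase genes were -3.16, -2.67 and -2.51 and no longer passed (edgeR adjusted p = 0.0698, 0.0654 and 0.0725), rhodanese-like 15 at -3.26 did not pass either, and the ammonium transporter was at -3.55. Without SR replicate 1 the dynein, TAT2, rhodanese-like, monooxygenase, methyltransferase and P450 genes did not pass (adjusted p = 0.0702, 0.0845, 0.0536, 0.0861, 0.0659 and 0.0656), and without SR replicate 2 the dynein, TAT2 and monooxygenase genes did not (0.0756, 0.0702 and 0.0729). The latex protein-like gene was at 4.63, 5.98 and 4.09 without SCK replicate 1, SCK replicate 2 and SR replicate 3 (adjusted p = 0.0541, 0.0640 and 0.115), and the pectinesterase-like gene missed the threshold without the same libraries (0.0542, 0.0572 and 0.0641). Without SCK replicate 2 the P450 and methyltransferase genes did not pass (0.0612 and 0.0659). By limma TAT2 and the monooxygenase gene did not pass (0.0695 and 0.0723), nor the pectinesterase-like gene with quantile normalization (0.0521).

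Markers of other tissues gave calls in both directions. Phloem genes rose in 6 and fell in 6 of 51 cases (13 and 7 adjusted over the list alone; list adjusted p = 0.507), but the list mixes kinds of protein. The rises were SIEVE ELEMENT OCCLUSION B-like genes, for sieve element proteins, and a PHLOEM PROTEIN 2-LIKE A9-like gene. The falls were F-box proteins and protein phosphatases caught by their names, such as F-box PP2-A13-like (CmoCh02G010570, log2 change -1.32 ± 0.12) and a PP2A phosphatase subunit (CmoCh03G001220, -1.10 ± 0.14). Root and endodermis genes rose in 4 and fell in 4 of 46 cases (7 and 6 adjusted over the list alone; list adjusted p = 0.990), with SHORT-ROOT-like (CmoCh07G006610) up by 1.52 ± 0.24 and scarecrow-like 4 (CmoCh03G007820) by 1.07 ± 0.13. Scarecrow-like 22 and 28 also rose, and scarecrow-like 1, 8 and genes named PAT1 fell. These members entered by product name, and whether they mark root tissue was not tested. Epidermis genes rose in 11 and fell in 4 of 88 cases (12 and 5 adjusted over the list alone; list adjusted p = 0.796). Their leading members, trichome birefringence-like 33 (CmoCh04G011590, log2 change 1.81 ± 0.23) and 36 (CmoCh04G015050, 1.04 ± 0.17), belong to a family that acetylates wall polysaccharides. The falls were a GLABRA2 expression modulator and trichome birefringence-like genes 9 and 33. Shoot apex genes rose in 3 and fell in 1 of 31 cases (5 and 1 adjusted over the list alone; list adjusted p = 0.602), with LET6 (CmoCh07G003200) up by 0.71 ± 0.15 and knotted-1-like 3 (CmoCh05G003680) down by 0.65 ± 0.14. WUSCHEL-related homeobox 4-like and knotted-1-like 7 also rose. Seed reserve genes rose in 2 and fell in 1 of 10 cases (2 and 2 adjusted over the list alone; list adjusted p = 0.602): an oleosin and a 2-isopropylmalate synthase of leucine synthesis (CmoCh14G008690, log2 change 0.52 ± 0.09) rose, and malate synthase (CmoCh13G008220) fell by 0.94 ± 0.18. Over fits without SCK replicates 1 and 2 and SR replicates 1, 2 and 3 in turn, edgeR called 7, 0, 5, 2 and 1 rises and 4, 5, 8, 5 and 2 falls of phloem genes (11 and 6 without TMM factors). In that order root genes gave 4, 2, 5, 2 and 1 rises and 4, 1, 3, 1 and 0 falls (8 and 2 without TMM factors). Epidermis genes gave 4, 5, 12, 2 and 1 rises and 1, 2, 4, 3 and 2 falls, so that falls outnumbered rises without SR replicate 2 or 3. Shoot apex genes gave 2, 0, 3, 1 and 0 rises and 0, 0, 0, 1 and 0 falls (5 and 0 without TMM factors), and seed reserve genes 1, 1, 2, 2 and 0 rises and 0, 1, 1, 0 and 0 falls. Without SR replicate 3 SHORT-ROOT-like, trichome birefringence-like 36 and the isopropylmalate synthase did not pass (adjusted p = 0.0606, 0.0634 and 0.0633). Malate synthase missed the threshold without SCK replicate 1 or SR replicate 2 or 3 (0.0550, 0.0512 and 0.0872) and LET6 without SCK replicate 2 or SR replicate 2 (0.0744 and 0.0675) or SR replicate 3. Knotted-1-like 3 passed without SR replicate 2 but not without SCK replicate 1 or 2 or SR replicate 1 or 3 (0.0567, 0.0754, 0.0577 and 0.0825), without TMM factors (0.0646) or by limma (0.0699).

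Heat shock and folding genes rose in 17 and fell in 19 of 157 cases (20 and 24 adjusted over the list alone; list adjusted p = 0.870), with the chloroplast chaperones dnaJ 20 (CmoCh17G000910) and dnaJ C76 (CmoCh19G010470) at log2 changes of -1.81 ± 0.13 and -1.71 ± 0.14. Touch and wound genes rose in 7 and fell in 5 of 74 cases (9 and 5 adjusted over the list alone; list adjusted p = 0.475), with calmodulin-like 1 (CmoCh02G005640) up by 1.39 ± 0.23 and cysteine proteinase inhibitor 8-like (CmoCh09G010620) at a log2 change of -3.20 ± 0.51. The other falls were CML21, CML48, MYC2-like and cysteine proteinase inhibitor 1-like. Sugar starvation genes rose in 7 and fell in 11 of 77 cases (10 and 14 adjusted over the list alone; list adjusted p = 0.0991), with trehalose-phosphate synthase 10 (CmoCh11G001070) at a log2 change of -1.23 ± 0.11 and synthase 5-like (CmoCh06G006550) up by 1.43 ± 0.18. Nitrate and phosphate transport genes rose in 3 and fell in 7 of 66 cases (4 and 10 adjusted over the list alone; list adjusted p = 0.324), with NRT1/PTR family 5.8-like (CmoCh14G006350) at a log2 change of -1.93 ± 0.26. The rises were a nitrate reductase gene and the NRT1/PTR family members 5.4 and 1.2-like. Flavonoid genes rose in 2 and fell in 4 of 27 cases (3 and 6 adjusted over the list alone; list adjusted p = 0.176), with an isoflavone 2'-hydroxylase-like gene (CmoCh20G009900) down by 1.06 ± 0.19 and an anthocyanidin glucosyltransferase-like gene (CmoCh01G013450) by 0.81 ± 0.15. The rises were isoflavone reductase-like genes, and the other falls were a further gene of that name and a further isoflavone 2'-hydroxylase-like gene. Fits without SCK replicates 1 and 2 and SR replicates 1, 2 and 3 in turn gave 6, 10, 16, 9 and 3 rises and 10, 11, 15, 12 and 6 falls of heat shock genes by edgeR (23 and 15 without TMM factors). In that order touch and wound genes gave 1, 3, 10, 4 and 0 rises and 3, 3, 7, 2 and 0 falls (11 and 4 without TMM factors). Sugar starvation genes gave 4, 5, 10, 4 and 4 rises and 10, 9, 9, 14 and 1 falls (10 and 9 without TMM factors). Nitrate and phosphate transport genes gave 2, 1, 4, 4 and 2 rises and 5, 7, 6, 4 and 2 falls, and flavonoid genes 2, 2, 2, 1 and 0 rises and 1, 1, 5, 3 and 0 falls. Without SR replicate 3 calmodulin-like 1, cysteine proteinase inhibitor 8-like and the isoflavone and anthocyanidin genes did not pass (adjusted p = 0.0578, 0.0655, 0.0592 and 0.0592), nor did the anthocyanidin gene without SCK replicate 1 or 2 (0.0501 and 0.0522). Median, mean and camera direction differed in sign in 8 lists, all uncalled: HD-Zip II, early auxin response, brassinosteroid, ethylene, cytokinin, root, heat shock and nitrate. The median changed sign under another scaling in 12 lists, again all uncalled: early auxin response, brassinosteroid, clock, ethylene, gibberellin, heat shock, jasmonate, nitrate, root, seed reserve, epidermis and sugar starvation.

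**Figure D3:**
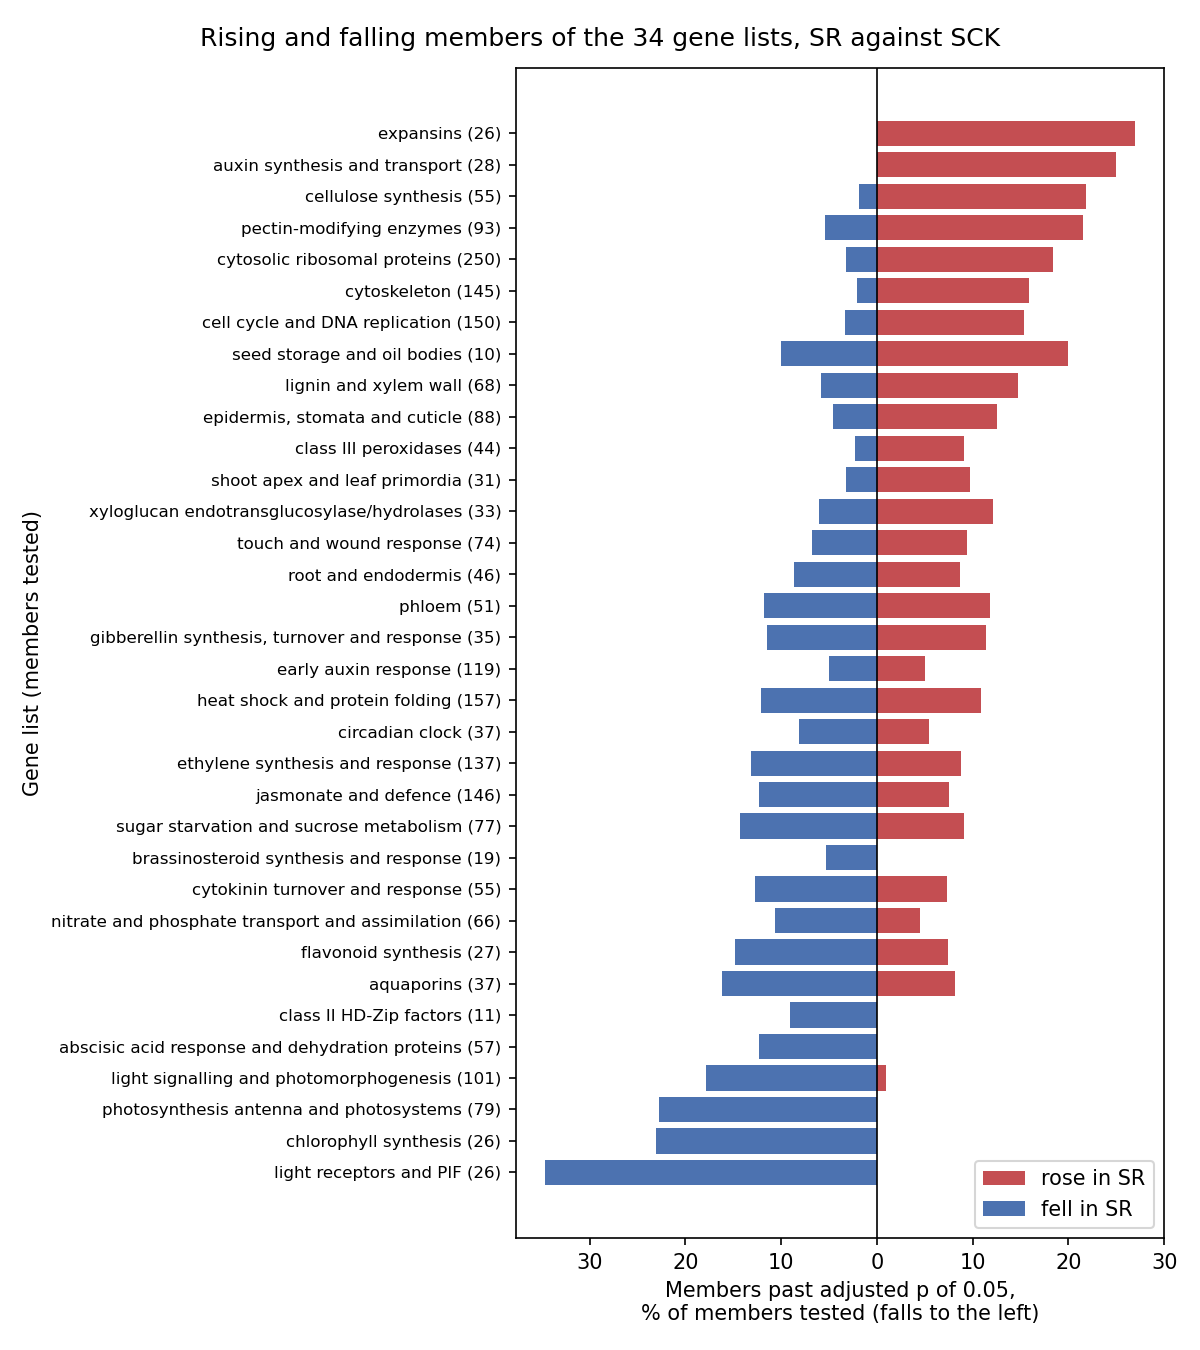
Bars give, for each of the 34 gene lists (vertical axis, with members tested), the percent of members called as rises (right) and as falls (left) by edgeR. Expansins are at the top, with 7 rises and 0 falls of 26, and light receptors and PIF at the bottom, with 9 falls and 0 rises of 26.

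Camera called 11 of the 34 lists, and 0 lists were called with an estimated correlation (smallest adjusted p = 0.427) or by fry in 1 direction (smallest adjusted p = 0.0513). Of the GO and KEGG terms, 81 were enriched by Fisher's exact test, 55 among the genes that rose and 26 among those that fell. That test takes genes as independent, so its p-values would be too small where members of a term move together. Cellulase activity held 9 rises among 13 tested genes where 1.03 were expected (adjusted p = 5.07e-05), and starch metabolic process 55 of 311 where 24.5 were expected (adjusted p = 2.54e-05). Circadian rhythm held 29 falls of 129 where 10.7 were expected (adjusted p = 0.000188), response to water deprivation 16 of 60 where 4.63 were expected (adjusted p = 0.00148) and antenna proteins 11 of 33 where 2.73 were expected (adjusted p = 0.00414). The clock list held 3 falls and 2 rises among 37 genes and was not called by camera (adjusted p = 0.198). Most falls of the circadian rhythm term therefore lie outside that list, and their overlap with the light lists was not examined. Without SCK replicate 3 or without SR replicate 3, 0 terms were enriched by edgeR calls, next to 80 by DESeq2 calls without SCK replicate 3; without SCK replicate 1, SCK replicate 2 and SR replicate 2 there were 18, 23 and 23. Circadian rhythm was among these each time (adjusted p = 0.0226, 0.00234 and 0.00225). Cellulase activity did not pass without SCK replicate 1 (0.850) or SR replicate 2 (0.378), starch metabolic process without SCK replicate 1 (0.121), water deprivation without SCK replicate 2 (0.0822) or SR replicate 2 (0.112), and antenna proteins without any of these libraries (0.345, 0.0641 and 0.835).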

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

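No alternative turned the sign of any of the 3375 called genes that it tested. This is weak evidence, since the groups did not overlap in 3359 of these genes. Leaving out a library could hardly turn such a sign, and the other alternatives refit the same 6 libraries. The choices of dropping TMM factors, dividing counts by 4, and running DESeq2 or limma without SCK replicate 3 were made after seeing the data. DESeq2 called 6026 genes (3048 rose, 2978 fell) and 135 terms, and without SCK replicate 3 3637 genes; 91 of its 252 calls in simulation were false. Limma on log2(FPKM + 1) called 1088 falls, with a pseudocount of 0.1 1055 and after rescaling FPKM to a common total 1028, and by limma 68.7% of calls were rises against 50.1%; without TMM factors 2602 genes rose (69.3%). These move with the scaling: the median of all genes was 0.13, 0.15, 0.15 and 0.14. With the replicate block 0 genes, 0 genes at least 2-fold and 0 terms were called (6564 genes at an unadjusted p under 0.05, smallest adjusted p = 0.0517). Deviations from the group mean correlated at -0.13, -0.23 and 0.09 between same-numbered libraries. Between libraries of unlike number they correlated at -0.13 to 0.24. These values are tied together by the group means, so they cannot show whether the numbers pair samples, and the labels do not say. Limma without SCK replicate 3 called 8 genes (5 rose, 3 fell), all 8 at least 2-fold, and 0 terms. With an estimated correlation or fry 0 lists were called.

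Leaving out 1 library gave 0 to 3437 genes, 0 to 1830 rises, 0 to 1607 falls, 0 to 1676 genes at least 2-fold, 0 to 111 terms and 10 to 13 lists; the cause was not tested. The lowest gene counts are without SCK replicate 3 (smallest adjusted p = 0.0547), and 0 terms were enriched there and without SR replicate 3. Without SCK replicate 3, 81 of the 85 named genes no longer passed by edgeR. The rest had not passed with all libraries either, so none passed there. Of the named genes, 6 no longer passed by limma, and 8 to 29 when another library was left out.

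Signs turned in 2 abundant uncalled genes. Expansin-A8-like (CmoCh15G001780, main log2 change -0.06) was 0.013 with quantile normalization, 0.071 without TMM factors, 0.065 without SCK replicate 1 and 0.079 without SR replicate 1, and ran from -0.75 to 0.28 over the libraries left out (without SR replicates 3 and 2). Xyloglucan protein 22-like (CmoCh10G004370, main -0.04) was 0.21 by limma and with a pseudocount of 0.1, 0.22 rescaled to a common total, 0.33 with quantile normalization, 0.070 with the block, 0.083 without TMM factors, 0.022 without SCK replicate 3, 0.0064 without SR replicate 1, from -0.35 to 0.28 over the libraries left out (without SCK replicates 1 and 2) and, without SCK replicate 3, 0.0075 by DESeq2 and 0.33 by limma. The cause was not tested. Robust priors were not run for lists, since camera takes none. At this depth with 3 replicates 22 of 100 simulated 2-fold changes were recovered; no other depth was simulated, and counts divided by 4 gave 3475 genes.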

Other observations

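The tests of blended reads or finished libraries, of a deposited copy of a library, of intermediate seedlings, of transcripts high in SCK replicate 1 and of the splits of the samples were chosen only after the results were seen. Terms of primary metabolism and protein turnover were also enriched among the calls, by the same one-sided Fisher's exact tests, which take genes as independent. Genes of amino sugar and nucleotide sugar metabolism, which supplies precursors of wall polysaccharides, rose in 42 of 193 cases (adjusted p = 2.54e-05). Glycolytic process held 35 rises of 192 where 15.1 were expected (adjusted p = 0.000816), the citrate cycle 19 of 82 where 7.21 were expected (adjusted p = 0.00487) and the proteasome 26 of 123 where 10.8 were expected (adjusted p = 0.00225). Falls were enriched in leucine catabolic process, with 15 of 50 where 3.86 were expected (adjusted p = 0.000859), in the peroxisome, with 19 of 84 where 6.49 were expected (adjusted p = 0.00218), and in fatty acid degradation, with 16 of 63 where 5.21 were expected (adjusted p = 0.00406). Unlike the proteasome, ubiquitin-protein transferase activity was enriched among falls, with 29 of 160 where 12.4 were expected (adjusted p = 0.00198), as was ubiquitin mediated proteolysis, with 34 of 230 where 19.0 were expected (adjusted p = 0.0230). By edgeR calls none of these terms passed without SCK replicate 3 or SR replicate 3. Leucine catabolism passed without SCK replicate 1, SCK replicate 2 and SR replicate 2 (adjusted p = 0.00665, 0.000643 and 0.00595). The proteasome (0.216, 0.121 and 0.516), the citrate cycle (0.309, 0.163 and 0.0970), fatty acid degradation (1, 0.247 and 0.873) and transferase activity (0.204, 0.256 and 0.0521) missed the threshold without each of these. Of these 3 fits, nucleotide sugar metabolism passed in that without SCK replicate 1 (0.0351, 0.215 and 0.209), and the other terms in that without SR replicate 2: glycolysis (0.0701, 0.0752 and 0.0307), the peroxisome (0.235, 0.157 and 0.0254) and ubiquitin mediated proteolysis (0.0668, 0.267 and 0.00595). Without TMM factors fatty acid degradation did not pass (0.0535).

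SCK replicate 3 lay between SCK replicates 1 and 2 in 97.1% of 1196 genes that differ at least 2-fold between those, against 76.8% for SR replicate 3 and 11.6% to 56.8% for the other libraries, with a median weight of replicate 1 of 0.35. A blend of the reads deposited for both is argued against by the 59 genes at least 3 times higher in replicate 1. In 35.6% of these the share of replicate 1 in replicate 3 was below 0.12. Those are the 21 genes described below, while the 59 were chosen without replicate 3. A second deposit of replicate 2 is argued against by a spread of 5.65 times the counting error between replicates 2 and 3. Each counting error here takes 1 read pair as 4 deposited counts, which was not established. A blend of plant material or RNA before library preparation may account for the position: in 123 genes where replicates 1 and 2 agree, replicate 3 spread around them by 2.27 times the counting error, where the same ratio was 3.55 to 6.87 for the other libraries. A blend of finished libraries also stays open, with a spread around the best blend of 2.47 times the counting error. If 1 read pair is worth fewer than 4 counts, these ratios are larger and speak less for either blend. Either blend needs the transcripts that are high in replicate 1 alone to have entered that library later. With either blend the control would hold fewer than 3 independent samples. The main test would then understate the spread within SCK, and its p-values would tend to be too small. Independent seedlings of an intermediate state stay open, because they set no bound on the range of shares (interquartile range 0.155).

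Photosynthesis genes were lower in SR but also differed within SCK. A lower share of green tissue as the whole cause gives 1 common fold only if the members are expressed in green tissue alone. That condition was not tested, so unequal folds cannot decide this explanation, and it stays open. The changes of the 45 abundant members ran from -3.22 to -0.05. Their squared deviations from a common fold were 3.35 times what their errors give, which lies between the bounds set in advance. The state that separates SCK replicate 1 from replicate 2 also stays open, since the SR mean lay at a median of -0.20 relative to SCK replicate 2, again between the bounds. An effect of the treatment is the biological explanation the design names, and it was not separated from these.

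In SCK replicate 1 alone, 21 genes took 2.87% of the counts, against 0.188% to 0.293% in the other libraries, and their median ratio to SCK replicate 2 was 9.43. They had been selected for a low share of replicate 1 in replicate 3, so their own share cannot test the explanations that follow. The difference in tissue or state that sets other genes higher in replicate 1 stays open: 24 genes at least 5 times higher there than in SCK replicate 2 and each SR library had a median share of 0.0174, but 19 of them are among the 21, and the other 5 had shares of 0.275 to 0.384. Reads of a repeated genomic unit carried into 1 library may contribute, and 52.4% of the 21 genes lie within 20 kb of another of them, which decides neither way. No other biological explanation was tested.

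The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3375 genes, 1450 genes changed at least 2-fold and 81 enriched terms, each reached by 1 of the 10 splits, and the highest other splits gave 3, 3 and 0. For called lists, 3 of the 10 splits gave at least the 11 of the real one, and the highest other gave 14.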
